A study of Mus musculus with 6 samples.

How the data were processed

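RNA-seq libraries were analysed from wild-type mouse neural stem progenitor cells collected 24 h after PTN or PBS, 3 libraries per group. Per the labels' protocols, RNA was isolated with an RNeasy column kit and 1.3 ug of total RNA per library went into a SMARTER mRNA library kit. Per the series title, PTN was added in a conditioned medium setting, of which no further detail is given, and the labels give PTN only as an abbreviation. Aligner, counting program, genome build and annotation are not given in the sources used here.

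The authors deposited 1 table of 22322 genes with an expected count and an FPKM value per library, 1 column of each for every library. The expected counts, as deposited, are estimated reads or fragments per gene, not scaled between libraries, and between 91.9% and 92.8% of them in each library are whole numbers within 0.005. The FPKM values, as deposited, are those counts per kilobase of gene and scaled by library depth, given to 2 decimals. The column names abbreviate the titles by the first letter of the group and the replicate number, and were matched to the samples on that basis. All columns with library values were matched. The table pairs gene identifiers with symbols, except for 16 genes, and gives annotation terms for each gene. The table holds no comparison by the authors.

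Groups were taken from the labels. Expected counts were rounded to whole numbers, genes were kept by edgeR's filterByExpr (13161 of 22322, or 59%). Libraries were scaled by TMM, the factors lying between 0.993 and 1.01. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3), PTN minus Control, with no further covariate. The p-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM values are scaled by TMM. The biological coefficient of variation was 0.208. Totals of 19267764 to 26341745 counts per library mean that 1 CPM stands for about 19 to 26 counts, so genes under 1 CPM rest on few counts. In 2037 of the tested genes (15.5%) some expected counts were fractional. This held for 5 of the named genes, Bid, Cflar, Cntnap2, Kif20a and Tm7sf2.

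The comparison, its test, 29 gene lists, the rule for named genes and most alternatives were set before the data were examined. The lists on cell identity and division were neural stem and progenitor identity, neuroblast and neuron, astrocyte, oligodendrocyte lineage, S phase, and G2 and mitosis. Those on signalling and metabolism were PTN with midkine and their reported receptors, Wnt targets, MAPK feedback and immediate early genes, FoxO targets, Notch pathway, cholesterol synthesis, unfolded protein and amino acid stress response, hypoxia and glycolysis, and p53 targets. Further lists were interferon response, NF-kB and cytokines, TGF-beta and BMP targets, and secreted growth and neurotrophic factors. The last were extracellular matrix and perineuronal proteoglycans, synapse and axon guidance, apoptosis, ribosomal proteins, mitochondrial DNA transcripts, nuclear oxidative phosphorylation, and markers of microglia, endothelial and mural cells, fibroblasts and meninges, and ependyma and choroid plexus. Lists with at least 5 tested members were tested on log2 CPM with limma's camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation, and fry. Within each list, p-values were also adjusted over the list alone. Terms of 10 to 500 tested genes were tested with a one-sided hypergeometric test against all tested genes with a term of the same source, and adjusted over terms. The sources were the 3 branches of the gene ontology and pathways, as the table gives them per gene.

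The rule for named genes took the 12 largest called changes in each direction among genes whose PTN and Control values did not overlap and whose mean over the libraries was at least 1 CPM, leaving out predicted gene models (2 higher and 0 lower were passed over). It then took up to 4 called members of each list by smallest p, or the member of smallest p where none was called, and always Ptn, Ptprz1, Alk, Ncl, Sdc3, Lrp1 and Mdk. Where a symbol stood for several genes, the one of highest mean was used. This named 108 genes, 96 of them called, and some of them are not reported here.

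Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in the same edgeR test, no filter, a filter of 1 CPM in 3 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, the replicate number as a block, an absolute log2 fold change of at least 1, an adjusted p under 0.1, and leaving out each library in turn. For the lists they were fry, an estimated correlation, the block, DESeq2 size factors, the filter of 1 CPM and leaving out each library. For the terms it was the 300 genes of smallest p in each direction. Chosen after seeing the data were the removal of a gene length trend, or of length and GC trends, from each library as offsets (natural splines with 4 degrees of freedom). So were leaving out mitochondrial DNA transcripts, a limma trend test on log2(FPKM + 1) of genes with FPKM of at least 1 in 3 libraries, and leaving out libraries for the terms. Effective gene length was derived from the ratio of expected counts to FPKM in libraries with FPKM of at least 1. GC content was taken from the longest transcript of each gene in the GENCODE M21 mouse transcripts, used for no other purpose. Both were known for 91.5% of the tested genes.

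The procedure was tested on simulated data for the 13161 tested genes. Counts were drawn from the real means, dispersions and library sizes, with 200 genes changed in each of 5 runs. It recovered 10.4%, 54.3% and 90.3% of genes changed 1.5-fold, 2-fold and 4-fold for the comparison of PTN with Control, and 8.04% of its calls were false. A simulated list raised 1.5-fold was called by camera (adjusted p = 6.47e-24) and 0 of 28 untouched lists were. Genes were drawn independently and lists at random, so this cannot show how camera behaves where members of a list vary together. A length trend of slope 0.15 given to the PTN libraries was estimated at 0.153 before and 0.0022 after its removal.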

Results

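RNA from wild-type mouse neural stem progenitor cells, which renew themselves and can form neurons, astrocytes and oligodendrocytes, was sequenced 24 h after treatment with PTN or with PBS, the Control. Each group had 3 libraries. The labels give PTN only as an abbreviation, and it is read here as pleiotrophin, the secreted heparin-binding growth factor encoded by Ptn. The amount of PTN added is not given in the sources used here. Expected counts per gene summed to 23530118, 26341745 and 21268297 in Control 1, Control 2 and Control 3, and to 25975205, 22331599 and 19267764 in PTN 1, PTN 2 and PTN 3. No label says whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

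Pearson's r of log2 CPM across genes, which are not independent replicates, lay between 0.961 and 0.987 in the 6 pairs within a group and between 0.93 and 0.966 in the 9 pairs between groups. The first principal component held 57.9% of the variance and separated the groups. No pair of libraries differed as little as sampling noise would allow, the smallest chi-square per degree of freedom being 11.9. Transcripts of mitochondrial DNA took 4.47, 7.47 and 5.76 percent of the counts in the 3 Control libraries and 8.12, 8.1 and 3.97 percent in the 3 PTN libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together reached 49.3, 102 and 80.3 CPM in the Control libraries and 30.3, 74.2 and 7.96 CPM in the PTN libraries, the last value being that of PTN 3.

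**Figure D1:**
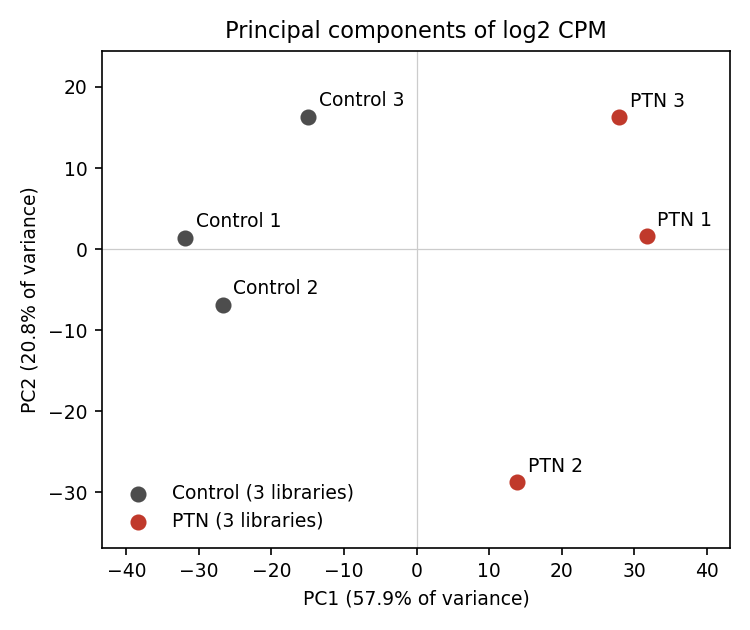
Principal components of log2 CPM over the 1000 genes of highest variance, with PC1 (57.9% of the variance) on the horizontal and PC2 (20.8%) on the vertical axis and one point per library, 3 Control in grey and 3 PTN in red. The Control libraries lie at PC1 values from -31.9 to -14.9 and the PTN libraries from 13.9 to 31.7.

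Which genes differ between cells given PTN and Control cells at 24 h is the comparison that the series' design names. After PTN the adhesion molecule gene Vcam1, the AMPA receptor gene Gria1, the guidance factor gene Sema3c and the neurotrophin gene Bdnf were 2.66-fold, 2.33-fold, 7.38-fold and 2.97-fold higher. The astrocyte gene Aldoc, the Notch target gene Nrarp and the nuclear corepressor gene Hr were 4.18-fold, 3.96-fold and 32.2-fold lower (n = 3 each). Of 13161 genes tested, 1052 were called at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 649 of them higher and 403 lower in PTN. A change of at least 2-fold was seen in 636 of the called genes, 427 higher and 209 lower. In all 1052 called genes the 3 PTN values lay wholly above or below the 3 Control values. They did so in 4327 of the tested genes, or 32.9%. The average over all ways of dividing the libraries into 3 and 3 is 10%. Genes vary together, so a single division can lie far from that average without any effect of PTN. At an unadjusted p under 0.05 by edgeR, divisions that mixed the groups had 34 to 2528 genes. The share of 32.9% is therefore no test against chance. The number of calls changed when single libraries were left out, being 348, 404, 331, 513, 1111 and 2177 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn. A refit without 1 library has fewer residual degrees of freedom. A call lost in it, here and below, therefore need not point to that library. Fold changes also rose with gene length, from a median log2 value of -0.24 in the shortest eighth of the genes to 0.30 in the longest, and 828 of the 1052 calls were kept when a length trend was removed from each library.

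**Figure D2:**
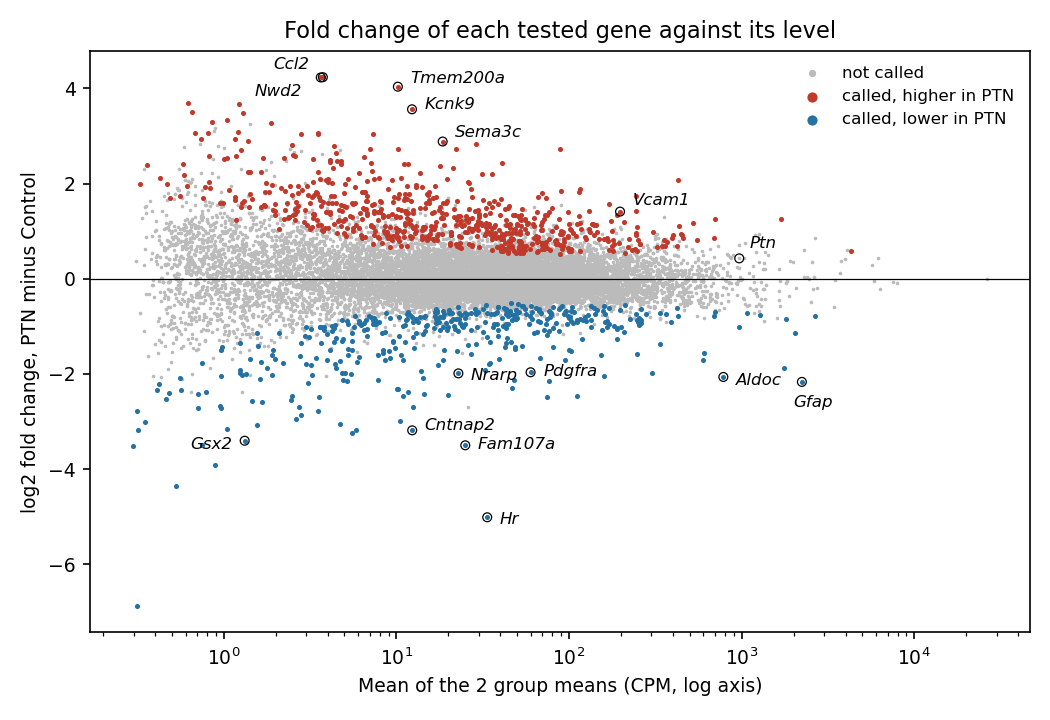
Log2 fold change (PTN minus Control) of each tested gene against the mean of its 2 group means in CPM on a log axis, with called genes in red (649 higher) or blue (403 lower), other genes in grey and circles around the labelled genes. Hr has a log2 fold change of -5.01 and Ccl2 one of 4.24, and the lowest point, Dio3, had no count in any PTN library, so its fitted value is not a bound.

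The 12 named genes with the largest rises were low in Control cells. Nwd2 rose 18.8-fold, from 0.365 ± 0.124 to 6.93 ± 3.35 CPM (SD, n = 3 each), with a log2 fold change of 4.23 ± 0.44 (SE, edgeR adjusted p = 0.00205). The transmembrane protein gene Tmem200a rose 16.4-fold (edgeR adjusted p = 0.00283), and Kcnk9, which encodes a two-pore potassium channel, 11.8-fold, from 1.92 ± 0.13 to 22.7 ± 10.6 CPM (edgeR adjusted p = 0.00187). Cyp26a1, the enzyme that degrades retinoic acid, rose 9.72-fold, the inflammatory caspase gene Casp4 8.31-fold, the morphogen gene Shh 8.25-fold, the protease gene Adamts19 8.19-fold and the potassium channel gene Kcnh8 7.64-fold, with edgeR adjusted p from 0.00344 for Casp4 to 0.00833 for Cyp26a1. The chemokine genes Ccl2 (18.8-fold), Ccl7 (10.1-fold) and Cxcl1 (8.29-fold) and the adipokine gene Adipoq (12.7-fold) completed the set. Without PTN 3 the folds of Ccl2, Ccl7 and Cxcl1 were 10.01, 4.66 and 4.92. The edgeR adjusted p of Ccl2 was 0.0117 but 0.0507 without Control 1, that of Ccl7 0.0353 but 0.0917, 0.108 and 0.127 without Control 1, Control 2 and Control 3, and that of Cxcl1 0.0122 but 0.0539 without Control 3. Adipoq had 0, 1 and 11 counts in Control 1, Control 2 and Control 3, and its edgeR adjusted p was 0.0342 but 0.0669 to 0.106 without any 1 of Control 1, Control 2, PTN 1 and PTN 2. Its fold was 8.35 without Control 1 and rested on 1 count without Control 3.

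The largest fall among the named genes was that of Hr, a nuclear corepressor bound by thyroid hormone and vitamin D receptors, from 65.1 ± 10.9 to 2.02 ± 0.931 CPM (SD, n = 3 each). Hr was 32.2-fold lower with a log2 fold change of -5.01 ± 0.32 (SE, edgeR adjusted p = 0.00041). Fam107a, an actin-associated gene of radial glia and astrocytes, was 11.3-fold lower, from 46 ± 3.98 to 4.1 ± 1.87 CPM (edgeR adjusted p = 0.00187). Cntnap2, a cell adhesion gene of the neurexin family, was 9.09-fold lower (edgeR adjusted p = 0.00041), with counts that were in part fractional. Gsx2, a homeobox gene of ventral telencephalic progenitors, was 10.6-fold lower, at 0.226 ± 0.0331 against 2.42 ± 0.262 CPM (edgeR adjusted p = 0.00204). The neuregulin receptor gene Erbb3 was 7.27-fold, the sulfotransferase gene Chst8 9.47-fold, the myosin kinase gene Mylk2 9.05-fold, the potassium channel gene Kcng4 8.32-fold, the transglutaminase gene Tgm1 7.91-fold and Ky 7.71-fold lower, with edgeR adjusted p from 0.000461 for Tgm1 to 0.00623 for Erbb3. Gjb6, which encodes the astrocyte gap junction protein connexin 30, was 8.4-fold lower (edgeR adjusted p = 0.0319, but 0.0751 to 0.11 without any 1 of Control 1, Control 2, Control 3 and PTN 1). The retinoid isomerase gene Rpe65 was 8.9-fold lower (edgeR adjusted p = 0.0432, but 0.102 to 0.141 without any 1 of Control 1, Control 2, Control 3 and PTN 1). Without PTN 2 the fall of Gjb6 was 29.8-fold, and Rpe65, with 2, 12 and 0 counts in PTN 1, PTN 2 and PTN 3, was then left with 2 counts in PTN.

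**Figure D3:**
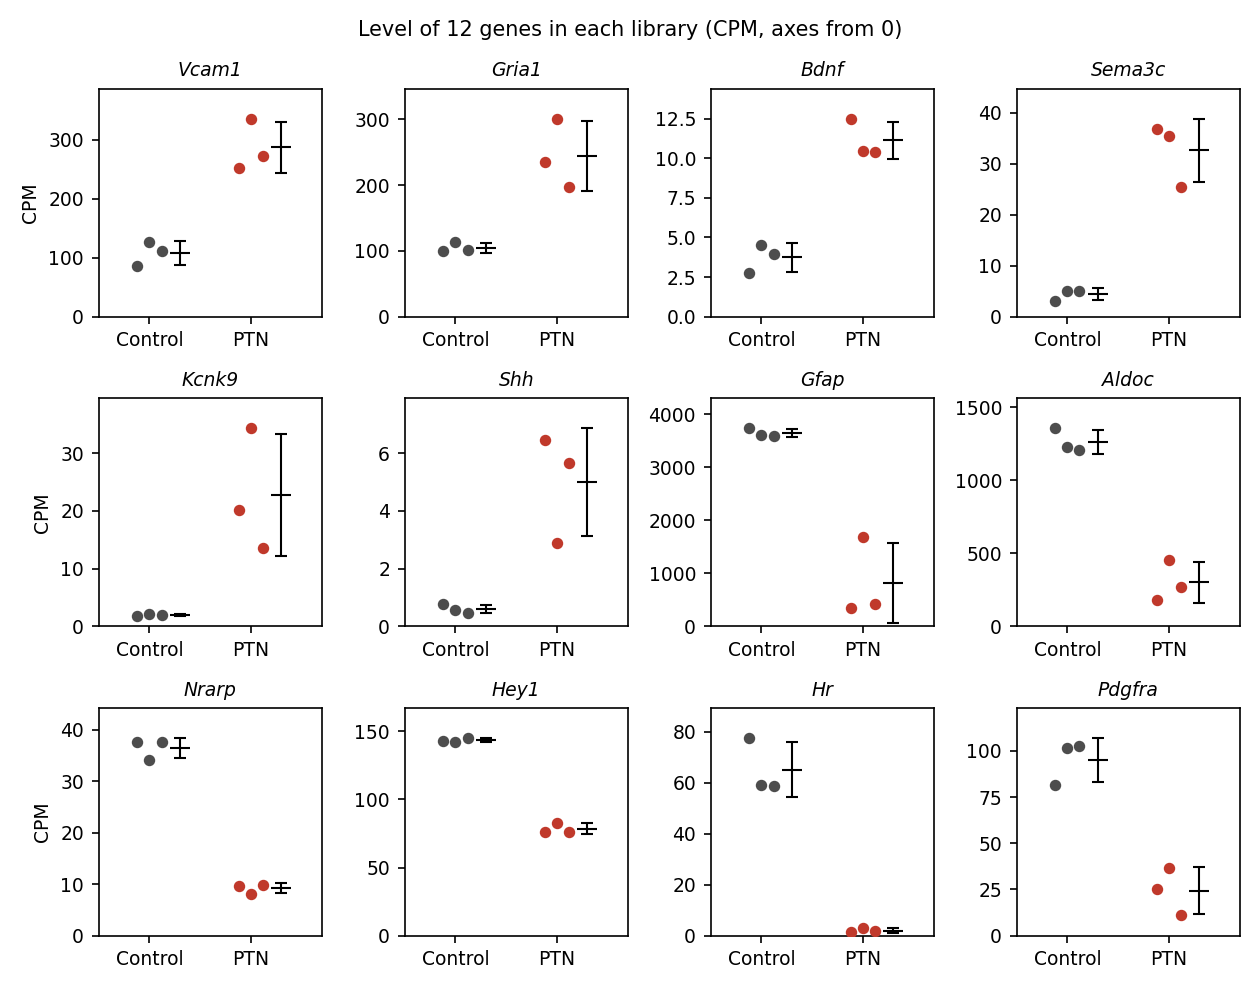
CPM of 12 genes in each of the 3 Control (grey) and 3 PTN (red) libraries, each panel with its own vertical axis from 0, bars showing the mean ± SD of the group. Vcam1, Gria1, Bdnf, Sema3c, Kcnk9 and Shh are higher and Gfap, Aldoc, Nrarp, Hey1, Hr and Pdgfra lower in every PTN library than in every Control library, and Gfap reaches 1685 CPM in PTN 2 against 342 and 414 CPM in PTN 1 and PTN 3.

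Of 18 tested astrocyte genes, 5 fell and 0 rose, and 6 fell when adjusted over the list alone. Aldoc, the brain isoform of the glycolytic enzyme aldolase, was 4.18-fold lower, from 1264 ± 81.5 to 303 ± 141 CPM (SD, n = 3 each, edgeR adjusted p = 0.00668). Acsl6, a fatty acid activating enzyme gene, was 2.4-fold lower (edgeR adjusted p = 0.0146, but 0.0509 and 0.0549 without Control 3 and PTN 1). Gfap, the intermediate filament gene of astrocytes and a member of the list, was singled out after its values were seen. It was 4.49-fold lower, at 813 ± 756 against 3652 ± 76.6 CPM (edgeR adjusted p = 0.047, but 0.0928 to 0.13 without any 1 of Control 1, Control 2, Control 3 and PTN 1), and without PTN 2 the fall was 9.67-fold. As a set the list was lower than other genes by limma's camera (adjusted p = 0.00683, median log2 fold change -0.21). The set's adjusted p = 0.585 with an estimated correlation, and by camera it was 0.0713 without PTN 1 and 0.0504 without PTN 3. The median was -0.84 without PTN 2 and -0.064 without PTN 1. Members called lower numbered 3, 3, 2, 2, 9 and 5 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn.

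In the oligodendrocyte lineage list 2 of 19 tested members fell and 1 rose, or 5 and 1 when adjusted over the list alone. Pdgfra, the growth factor receptor of oligodendrocyte precursors, was 3.9-fold lower, from 95.3 ± 11.9 to 24.4 ± 12.6 CPM (SD, n = 3 each, edgeR adjusted p = 0.0145, but 0.0533 without PTN 1). Cspg4, another precursor marker, was 1.81-fold lower (edgeR adjusted p = 0.0169, but 0.0611, 0.0771 and 0.0627 without Control 1, Control 3 and PTN 1). Opalin, a myelin gene, was 5.84-fold higher, at 2.9 ± 1.77 against 0.495 ± 0.198 CPM (edgeR adjusted p = 0.0259, but 0.051 to 0.108 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). The set was lower by limma's camera (adjusted p = 0.0401, median log2 fold change -0.32), but had an adjusted p = 0.585 with an estimated correlation. By camera its adjusted p was 0.142 without Control 1 and 0.196 without PTN 3, 0.0571 with the length trend removed and 0.163 with length and GC trends removed. Members called lower numbered 1, 2, 1, 0, 4 and 5 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn.

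Genes of neural stem and progenitor identity went in both directions, with 3 of 22 tested members higher and 1 lower, or 5 and 2 when adjusted over the list alone. The intermediate filament gene Vim was 1.5-fold higher (edgeR adjusted p = 0.0482, but 0.0818 to 0.209 without any 1 of Control 1, Control 2, Control 3 and PTN 1). The growth factor receptor gene Egfr was 1.76-fold higher (edgeR adjusted p = 0.0276, but 0.0527 to 0.128 without any 1 of Control 1, Control 2, Control 3 and PTN 1). The hyaluronan receptor gene Cd44 was 1.65-fold higher (edgeR adjusted p = 0.0276, but 0.0837 to 0.105 without any 1 of Control 1, Control 2, Control 3 and PTN 1). Within the Notch pathway list 3 of 16 tested members fell and 0 rose, or 3 and 2 when adjusted over the list alone. Those that fell are known Notch targets. Nrarp was 3.96-fold lower, from 36.5 ± 1.98 to 9.2 ± 0.946 CPM (SD, n = 3 each, edgeR adjusted p = 0.00095), and Hey1 1.83-fold lower, from 144 ± 1.45 to 78.4 ± 3.96 CPM (edgeR adjusted p = 0.00665). Hes5 was 3.32-fold lower (edgeR adjusted p = 0.0151, but 0.064, 0.0597 and 0.0539 without Control 1, Control 3 and PTN 1). Neither set passed limma's camera (adjusted p = 0.286 for stem and progenitor genes and 0.201 for the Notch pathway), but the Notch pathway list was lower by limma's fry (adjusted p = 0.0387), with 0.585 by camera with an estimated correlation. Its median log2 fold change was only -0.076, with 9 members negative and 7 positive, so the list did not fall as a whole. Without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, 0, 0, 0, 0, 5 and 5 stem and progenitor genes were called higher and 0, 1, 0, 0, 2 and 2 lower, and 0, 0, 0, 0, 2 and 1 Notch pathway genes higher and 2, 3, 2, 2, 5 and 3 lower.

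In the neuroblast and neuron list 5 of 24 tested members rose and 2 fell, or 9 and 5 when adjusted over the list alone. The presynaptic adhesion gene Nrxn3 rose 4.65-fold (edgeR adjusted p = 0.00291), the homeobox gene Prox1 2.5-fold (edgeR adjusted p = 0.00922) and the growth cone gene Gap43 2.64-fold (edgeR adjusted p = 0.00985, but 0.0504 without Control 1). The proneural gene Neurog2 was lower, at 2, 1 and 0 counts in PTN 1, PTN 2 and PTN 3 against 13, 17 and 10 in Control 1, Control 2 and Control 3 (edgeR adjusted p = 0.0178, but 0.0657, 0.07 and 0.0557 without Control 1, Control 2 and Control 3). Of 26 tested genes of synapses and axon guidance 7 rose and 1 fell, or 12 and 2 when adjusted over the list alone. The secreted guidance factor gene Sema3c rose 7.38-fold, from 4.42 ± 1.16 to 32.6 ± 6.24 CPM (SD, n = 3 each, edgeR adjusted p = 0.00135). The AMPA receptor gene Gria1 rose 2.33-fold, from 105 ± 7.41 to 244 ± 52.9 CPM (edgeR adjusted p = 0.00665). The guidance receptor gene Robo1 rose 2.27-fold (edgeR adjusted p = 0.00504) and the NMDA receptor gene Grin2b 2.49-fold (edgeR adjusted p = 0.0155, but 0.0509 to 0.0621 without any 1 of Control 1, Control 2, Control 3 and PTN 1). The synapse and guidance set was higher by limma's camera (adjusted p = 0.00207, median log2 fold change 0.45), but had an adjusted p = 0.404 with an estimated correlation. The neuroblast and neuron set did not pass camera (adjusted p = 0.419). Synapse and guidance genes called higher numbered 3, 4, 3, 5, 6 and 13 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn. In the same order 2, 3, 3, 3, 4 and 7 neuroblast and neuron genes were called higher and 0, 0, 0, 1, 1 and 3 lower. With the length trend removed the median of the synapse and guidance list was 0.27.

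Of 20 tested genes of G2 and mitosis 10 fell and 0 rose, and 11 fell when adjusted over the list alone. The ubiquitin-conjugating enzyme gene Ube2c was 1.68-fold lower, from 117 ± 7.49 to 69.8 ± 8.71 CPM (SD, n = 3 each, edgeR adjusted p = 0.0209, but 0.0622, 0.0561 and 0.0743 without Control 1, Control 2 and Control 3). The mitotic kinase gene Aurka was 1.94-fold lower (edgeR adjusted p = 0.0241, but 0.0743, 0.0733 and 0.0532 without Control 1, Control 3 and PTN 1). The spindle checkpoint kinase gene Bub1b was 1.62-fold lower (edgeR adjusted p = 0.021, but 0.0534, 0.0676 and 0.0911 without Control 1, Control 2 and Control 3). Of 20 tested genes of S phase and DNA replication 2 fell and 0 rose, and 3 fell when adjusted over the list alone, while 19 had a negative log2 fold change. Those called were Rrm2, a subunit of ribonucleotide reductase, 1.9-fold lower (edgeR adjusted p = 0.0354, but 0.0646 to 0.103 without any 1 of Control 1, Control 2, Control 3 and PTN 1), and Cdc45. Cdc45, a replication fork gene, was 1.63-fold lower (edgeR adjusted p = 0.0409, but 0.0648 to 0.122 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). Both sets were lower by limma's camera (adjusted p = 1.08e-05 for G2 and mitosis and 6.21e-05 for S phase), with median log2 fold changes of -0.65 and -0.44, and each had an adjusted p = 0.585 with an estimated correlation. Without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, 0, 2, 0, 3, 7 and 11 genes of G2 and mitosis and 0, 0, 0, 0, 1 and 7 of S phase were called lower, while the median of the G2 and mitosis list ranged over -0.74 to -0.53.

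**Figure D4:**
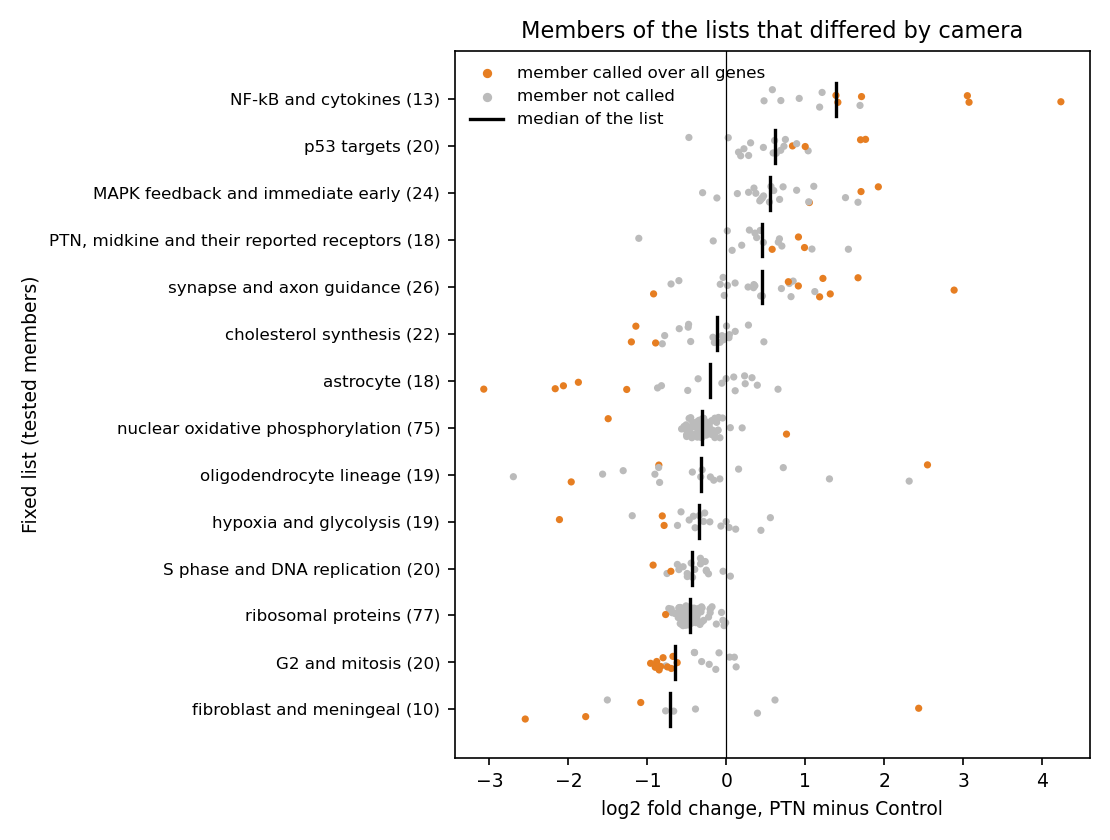
Log2 fold change (PTN minus Control, horizontal axis) of each tested member of the 14 lists, of 28 tested, that differed from other genes by camera with a preset correlation, one line per list with its number of tested members, called members in orange, other members in grey and the median as a black bar. The NF-kB and cytokine list has the highest median, 1.39, and the fibroblast and meningeal list the lowest, -0.72.

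Ptn itself was at 825 ± 183 CPM in Control and 1111 ± 187 CPM in PTN cells (SD, n = 3 each), and its difference was not called (log2 fold change 0.43 ± 0.21 SE, edgeR adjusted p = 0.223). The reported PTN receptor genes Ptprz1 (1747 CPM in Control and 2245 CPM in PTN), Ncl (358 and 495 CPM), Sdc3 (511 and 585 CPM) and Lrp1 (657 and 663 CPM) were not called, nor was the related growth factor gene Mdk (22.9 and 20.4 CPM). Their edgeR adjusted p ranged from 0.321 for Ptprz1 to 0.972 for Lrp1. Alk, another reported receptor, was at 0.617 ± 0.0299 and 1.81 ± 0.838 CPM (edgeR adjusted p = 0.0674). Of 18 tested members of the list of PTN, midkine and their reported receptors 3 rose and 0 fell, and 8 rose when adjusted over the list alone. Nrp1, a coreceptor for semaphorins and growth factors, was 1.99-fold higher (edgeR adjusted p = 0.0127, but 0.0578, 0.0527 and 0.0644 without Control 1, Control 2 and Control 3). The integrin gene Itgav was 1.88-fold higher (edgeR adjusted p = 0.0342, but 0.0981 to 0.131 without any 1 of Control 1, Control 2, Control 3 and PTN 1). Another integrin gene, Itga6, was 1.49-fold higher (edgeR adjusted p = 0.0482, but 0.0909 to 0.179 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). The set was higher by limma's camera (adjusted p = 0.00372, median log2 fold change 0.45), but had an adjusted p = 0.404 with an estimated correlation. Members called higher numbered 0, 0, 0, 1, 6 and 4 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn.

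Of 13 tested genes of the NF-kB and cytokine list 6 rose and 0 fell, and 12 rose when adjusted over the list alone. Vcam1 rose 2.66-fold, from 108 ± 20.6 to 287 ± 43.2 CPM (SD, n = 3 each, edgeR adjusted p = 0.00515). The chemokine gene Cxcl5 rose 8.41-fold to 1.46 ± 0.496 CPM (edgeR adjusted p = 0.009), and Tnfaip3, a feedback inhibitor of NF-kB, 3.27-fold (edgeR adjusted p = 0.0118, but 0.0504, 0.0596 and 0.0534 without Control 1, Control 2 and Control 3). Of 20 tested p53 targets 4 rose and 0 fell, and 11 rose when adjusted over the list alone. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose 3.25-fold, from 7.7 ± 1.76 to 25 ± 6.05 CPM (edgeR adjusted p = 0.00638), and the membrane protein gene Perp 3.39-fold (edgeR adjusted p = 0.00672). Of 24 tested genes of MAPK feedback and immediate early response 3 rose and 0 fell, and 6 rose when adjusted over the list alone. The transcription factor genes Egr3 and Fosl2 rose 3.79-fold (edgeR adjusted p = 0.00475) and 2.07-fold (edgeR adjusted p = 0.00665). These 3 sets were higher by limma's camera (adjusted p = 5.34e-08, 9.08e-05 and 0.000855), with median log2 fold changes of 1.39, 0.62 and 0.56. Their adjusted p = 0.404, 0.404 and 0.585 with an estimated correlation. Without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, the members called higher were 3, 4, 3, 6, 7 and 6 for NF-kB and cytokines, 2, 3, 2, 3, 5 and 6 for p53 targets and 2, 2, 2, 4, 9 and 3 for MAPK and immediate early genes.

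In the apoptosis list 4 of 18 tested members rose and 0 fell, or 5 and 1 when adjusted over the list alone. Bcl2, Mcl1 and Cflar, which oppose cell death, rose 2.18-fold, 1.62-fold and 1.74-fold, and Bid, which promotes it, 1.61-fold, the counts of Cflar and Bid being in part fractional. Their edgeR adjusted p was 0.0441, 0.0324, 0.0281 and 0.0496. It was 0.106 to 0.17 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2 for Bcl2. For Mcl1 it was 0.0997 to 0.146 without any 1 of Control 1, Control 2, Control 3 and PTN 1. For Cflar it was 0.0807 to 0.12 without any 1 of Control 1, Control 2, Control 3 and PTN 1, and for Bid 0.0596 to 0.191 without any 1 of Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3. Of 23 tested interferon response genes 1 rose and 0 fell, and 1 rose when adjusted over the list alone. This was Cxcl10, a chemokine gene, 3.85-fold higher (edgeR adjusted p = 0.0113, but 0.0567 and 0.0534 without Control 1 and Control 3). In the list of the unfolded protein and amino acid stress response 1 of 22 tested members rose and 1 fell, or 3 and 2 when adjusted over the list alone. Ddit3, a transcription factor gene of that response, was 1.83-fold higher (edgeR adjusted p = 0.0281, but 0.0507 to 0.162 without any 1 of Control 1, Control 2, Control 3 and PTN 2). Phgdh, an enzyme of serine synthesis, was 1.82-fold lower (edgeR adjusted p = 0.0297, but 0.0581 to 0.0989 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). None of these sets passed limma's camera (adjusted p = 0.31 for apoptosis, 0.78 for the interferon response and 0.609 for the unfolded protein list). The interferon list had a median log2 fold change of 0.12 while camera put it on the lower side. Apoptosis genes called higher numbered 0, 0, 0, 0, 3 and 3 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, interferon genes 0, 1, 0, 1, 1 and 2, and unfolded protein genes called higher 0, 0, 0, 1, 1 and 2 and lower 0, 0, 0, 0, 0 and 2.

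Among secreted growth and neurotrophic factors 4 of 29 tested members rose and 0 fell, or 6 and 2 when adjusted over the list alone. Bdnf, the brain-derived neurotrophic factor gene, rose 2.97-fold, from 3.75 ± 0.904 to 11.1 ± 1.19 CPM (SD, n = 3 each, edgeR adjusted p = 0.00665). The platelet-derived growth factor gene Pdgfa rose 2.62-fold (edgeR adjusted p = 0.0122, but 0.0603 without Control 3). In the list of extracellular matrix and perineuronal proteoglycans 5 of 25 tested members rose and 5 fell, or 8 and 6 when adjusted over the list alone. The fibronectin gene Fn1 was 2.18-fold lower (edgeR adjusted p = 0.00759) and the basement membrane collagen gene Col4a1 2.15-fold lower (edgeR adjusted p = 0.0127, but 0.0548 without Control 3). The metalloproteinase inhibitor gene Timp1 was 2.07-fold higher (edgeR adjusted p = 0.00578) and Sparc, a secreted matrix-binding protein gene, 1.77-fold higher (edgeR adjusted p = 0.0103, but 0.0795 and 0.0941 without Control 2 and Control 3). Of 14 tested TGF-beta and BMP targets 3 rose and 0 fell, and 4 rose when adjusted over the list alone, the transcription factor gene Atoh8 being 5.03-fold higher (edgeR adjusted p = 0.00344). None of these sets passed limma's camera (adjusted p = 0.223 for growth factors, 0.419 for matrix genes and 0.0828 for TGF-beta and BMP targets). The last was 0.0184 without PTN 1, 0.0376 with a filter of 1 CPM in 3 libraries and 0.0437 with the length trend removed, but 0.0849 with length and GC trends removed, 0.291 without PTN 2 and 0.585 with an estimated correlation. Without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, 2, 2, 1, 2, 5 and 5 growth factor genes and 1, 1, 1, 1, 3 and 3 TGF-beta and BMP targets were called higher, and 2, 1, 1, 2, 8 and 6 matrix genes higher and 2, 3, 1, 2, 4 and 5 lower.

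All 77 tested ribosomal protein genes had a negative log2 fold change, with a median of -0.46. Their share of all counts was 3.65, 3.18 and 3.11 percent in the 3 Control libraries and 2.53, 2.06 and 2.54 percent in the 3 PTN libraries. One gene, Rpsa, which encodes a ribosomal protein and laminin receptor, was called, 1.7-fold lower (edgeR adjusted p = 0.0322, but 0.075 to 0.098 without any 1 of Control 1, Control 2, Control 3 and PTN 1), and 43 fell when adjusted over the list alone. Ribosomal protein genes have many processed pseudogenes, with which they can share reads. Of 75 tested nuclear genes of oxidative phosphorylation 72 had a negative log2 fold change, with a median of -0.31, and 1 rose and 1 fell, or 0 and 0 when adjusted over the list alone. They were the cytochrome oxidase subunit genes Cox6b2, 1.7-fold higher (edgeR adjusted p = 0.0484, but 0.0514 to 0.217 without any 1 of Control 2, Control 3, PTN 1, PTN 2 and PTN 3), and Cox7a1. The latter was 2.82-fold lower (edgeR adjusted p = 0.0432, but 0.0513 to 0.129 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). Both sets were lower by limma's camera (adjusted p = 1.8e-14 and 9.64e-08), and each had an adjusted p = 0.585 with an estimated correlation. With the length trend removed the medians were -0.27 and -0.14. Called lower were 0, 0, 0, 0, 1 and 18 ribosomal protein genes and 0, 0, 0, 0, 0 and 13 oxidative phosphorylation genes without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn. Of 13 tested transcripts of mitochondrial DNA 0 were called by edgeR and 0 had an unadjusted p under 0.05, or 0 called higher and 0 lower by DESeq2. The gene of smallest p, mt-Atp8, was at 127 ± 57.3 and 247 ± 132 CPM (edgeR adjusted p = 0.217). Their set did not pass camera (adjusted p = 0.286), but its adjusted p was 0.00147 without PTN 3, when 4 members were called higher, and 0.0437 with the length trend removed. It was 0.487 with length and GC trends removed and 0.815 with an estimated correlation. The median log2 fold change was 0.36, and 0.078 with both trends removed. With each library left out it ranged from 0.13 without PTN 1 to 0.71 without PTN 3.

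Of 19 tested genes of hypoxia and glycolysis 3 fell and 0 rose, or 4 and 1 when adjusted over the list alone. Pfkl, the liver-type phosphofructokinase gene, was 1.75-fold lower (edgeR adjusted p = 0.0179, but 0.0567 and 0.0692 without Control 1 and Control 3). Ldha, the lactate dehydrogenase A gene, was 1.73-fold lower, from 880.2 ± 85 to 509.8 ± 124 CPM (SD, n = 3 each, edgeR adjusted p = 0.0482, but 0.0648 to 0.135 without any 1 of Control 1, Control 2, Control 3, PTN 1 and PTN 2). Of 22 tested genes of cholesterol synthesis 3 fell and 0 rose, or 5 and 0 when adjusted over the list alone. Tm7sf2, a sterol reductase gene with counts in part fractional, was 2.3-fold lower (edgeR adjusted p = 0.0064). Mvd, the mevalonate diphosphate decarboxylase gene, was 2.21-fold lower (edgeR adjusted p = 0.0247, but 0.0616 to 0.0871 without any 1 of Control 1, Control 3, PTN 1 and PTN 2). Both sets were lower by limma's camera (adjusted p = 0.00809 and 0.0108), with adjusted p = 0.585 for each with an estimated correlation, and by camera 0.0611 and 0.341 without PTN 2. The median log2 fold change of the cholesterol synthesis list was -0.12, and ranged from -0.33 without PTN 3 to 0.0054 without PTN 2. Genes of hypoxia and glycolysis called lower numbered 0, 1, 0, 3, 2 and 5, and those of cholesterol synthesis 1, 2, 1, 1, 2 and 9, without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn.

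Among FoxO targets and among Wnt and beta-catenin targets no member was called by edgeR, over all genes or when adjusted over the list alone. An unadjusted p under 0.05 was found in 2 of 16 tested FoxO targets and 2 of 12 tested Wnt targets, and DESeq2 called 1 of the FoxO targets higher and 1 lower, and 0 of the Wnt targets in either direction. The members of smallest p were the insulin receptor gene Insr, at 76.2 ± 10.1 in Control and 119.7 ± 23.4 CPM in PTN (SD, n = 3 each, edgeR adjusted p = 0.066), and Notum. Notum, which encodes an inhibitor of Wnt proteins, was at 1.02 ± 0.342 and 2.4 ± 1.01 CPM (edgeR adjusted p = 0.114). Neither set passed limma's camera (adjusted p = 0.722 and 0.525).

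Markers of other cell types were also measured. Of 8 tested endothelial and mural markers 2 fell and 0 rose, or 3 and 1 when adjusted over the list alone. Pdgfrb, a receptor of pericytes, was 5.62-fold lower, from 6.06 ± 0.564 to 1.08 ± 0.158 CPM (SD, n = 3 each, edgeR adjusted p = 0.00187). The smooth muscle actin gene Acta2 was 4.95-fold lower, from 16.7 ± 1.08 to 3.37 ± 1.55 CPM (edgeR adjusted p = 0.00649). Of 10 tested fibroblast and meningeal markers 3 fell and 1 rose, or 5 and 1 when adjusted over the list alone. Slc6a13, a GABA transporter gene of leptomeningeal cells, was 5.84-fold lower (edgeR adjusted p = 0.00313) and the matrix gene Ogn 5.41-fold higher, at 12 ± 4.09 against 2.2 ± 0.885 CPM (edgeR adjusted p = 0.00665). The fibroblast and meningeal set was lower by limma's camera (adjusted p = 0.0401, median log2 fold change -0.72), but had an adjusted p = 0.404 with an estimated correlation. By camera its adjusted p was 0.0594, 0.0646 and 0.0951 without Control 1, Control 3 and PTN 2, 0.0513 with the length trend removed and 0.115 with length and GC trends removed. The endothelial and mural set did not pass limma's camera (adjusted p = 0.103, and 0.585 with an estimated correlation), with a median log2 fold change of -0.51 that ranged over -0.80 to -0.056 with each library left out. Its members depended on the filter. With 1 CPM in 3 libraries the set passed (adjusted p = 0.0181, median -0.98), and with no filter the median over 14 members was 0.23. Fibroblast and meningeal markers called lower numbered 1, 2, 1, 1, 2 and 5 without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, and endothelial and mural markers 2, 2, 2, 2, 3 and 3. Only 4 of 15 microglia and macrophage markers were high enough to be tested, too few for a set test, and edgeR called 0 of them on either adjustment, 0 having an unadjusted p under 0.05 and DESeq2 calling 0 higher and 0 lower. Of 6 tested ependymal and choroid plexus markers edgeR called 0 on either adjustment, 2 having an unadjusted p under 0.05 and DESeq2 calling 0 higher and 0 lower. The transthyretin gene Ttr was at 1.03 ± 0.944 and 6.35 ± 8.19 CPM (edgeR adjusted p = 0.138, set by camera 0.223).

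Over the 28 lists with enough members for a set test, limma's camera with its preset correlation called 14, of which 5 were higher and 9 lower in PTN. With an estimated correlation it called 0, with 2 at an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way, called 6 lists, of which 5 were among the 14. These were PTN, midkine and their receptors (adjusted p = 0.0153), p53 targets (0.0168), NF-kB and cytokines (0.0241), synapse and axon guidance (0.0168) and fibroblast and meningeal markers (0.0168), and the other was the Notch pathway. Another of the 10 ways of dividing the 6 libraries into 3 and 3, with Control 1, Control 2 and PTN 1 on one side, gave 15 lists by the preset correlation.

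The annotation terms that the deposited table gives for each gene were tested for enrichment among the called genes with a one-sided hypergeometric test over 3675 terms. Among higher genes 172 terms were enriched at a Benjamini-Hochberg adjusted p under 0.05. Extracellular matrix came first, with 36 of its 183 tested genes called higher against 9.12 expected (exact hypergeometric adjusted p = 3.35e-09). The term collagen-containing extracellular matrix was enriched on both sides, with 32 of 211 genes called higher against 10.5 expected and 19 called lower against 6.55 (exact hypergeometric adjusted p = 7.34e-06 and 0.0122). Cell adhesion held 52 of 373 genes (exact hypergeometric adjusted p = 9.02e-09). Among terms of neuronal signalling, neuroactive ligand-receptor interaction held 24 of 116 genes, neuron projection 49 of 400 and ion channel activity 20 of 102. Response to hypoxia, by the table's terms, held 20 of 157 genes called higher against 7.71 expected (exact hypergeometric adjusted p = 0.00552), while the fixed list of hypoxia and glycolysis had 0 called higher and 3 lower. Chemokine-mediated signaling held 7 of 17 genes (exact hypergeometric adjusted p = 0.00118). Among lower genes 15 terms were enriched, among them cell division with 31 of 346 genes against 10.6 expected (exact hypergeometric adjusted p = 0.000296), spindle with 20 of 191 and glial cell migration with 6 of 12. Without Control 1, Control 2, Control 3, PTN 1, PTN 2 and PTN 3 in turn, 18, 24, 14, 81, 192 and 107 terms were enriched among higher genes and 0, 1, 0, 3, 8 and 52 among lower genes. Fold changes rose with gene length, of which the hypergeometric test takes no account. The terms were not retested with the length trend removed, so a share of length in these enrichments stays open.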

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

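The corrections for length and GC, the omission of mitochondrial DNA transcripts, the FPKM test and the omission of libraries for the terms were chosen only after the results were seen. No gene among the 1052 calls changed sign in any of the 18 refits that tested it. The refits without a library could hardly show such a change. In all called genes the PTN values already lay wholly above or below the Control values. The number of calls lay between 877 and 1125 under the 3 other scalings, both other filters, limma-voom, removal of the length trend, omission of mitochondrial DNA transcripts and the FPKM test. DESeq2 called 1852 genes (1087 higher and 765 lower), and removal of length and GC trends gave 1923 (1014 and 909), the cause of either not being tested. Stricter and looser thresholds gave 636 (427 and 209) at an absolute log2 fold change of at least 1 and 1913 (1089 and 824) at an adjusted p under 0.1. Leaving out each library in turn gave 331 to 2177 calls, 201 to 1273 higher and 130 to 904 lower, and 14 to 192 terms for higher and 0 to 52 for lower genes. The 300 genes of smallest p gave 48 and 4 terms. The cause of the lower and higher counts without single libraries was not tested, nor was that of the fewer terms. Of 96 named genes called, 42 kept their call in each refit that tested them and 54 lost it without at least 1 library.

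Of the list tests, fry called 6 and an estimated correlation 0 (2 at an unadjusted p under 0.05), against 14, the cause not being tested, while leaving out each library gave 11 to 14. With the replicate number as a block 726 genes were called, 454 higher and 272 lower, of which 660 were among the 1052, and 14 lists. Of the 96 named genes called, 19 lost their call with the block. Deviations of same-numbered libraries from their group means correlated at -0.51, 0.36 and -0.0049, and 2 of the 6 libraries correlated best with their own number, so the numbers are not taken to pair the libraries.

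Results that were not called changed sign under some settings, and the cause was not tested. The log2 fold change of Lrp1 was -0.032 with upper-quartile scaling, -0.00060 with the block, -0.00034 with limma-voom, -0.39 with the length trend removed, -0.17 with length and GC trends removed, and -0.16 to 0.16 with each library left out. That of Mdk was 0.011 and 0.15 with these trends removed and -0.29 to 0.032 with each library left out. With length and GC trends removed Ncl was at -0.028 and Ptprz1 at -0.019. Camera's direction changed for the interferon response (median log2 fold change 0.12, and 0.070 with length, 0.12 with length and GC trends removed, and -0.15 to 0.28 with libraries left out), which fry put on the higher side, and for the unfolded protein response (-0.033 with length and GC trends removed), and with libraries left out for neuroblast and neuron genes (0.14 to 0.40) and FoxO targets (-0.13 to 0.040). Genes under 1 CPM rest on few counts, and 1.5-fold changes were recovered in 10.4% of simulated cases, with fewer genes changed than were called in the data. The alternatives planned for a table of normalized values alone, other pseudocounts and another filter, were not needed.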

Other observations

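The tests of length and GC trends, of the thyroid hormone and glucocorticoid target lists and of the number of called genes under other splits were chosen only after the results were seen. The target lists were written after Hr, Hif3a and Fam107a were seen to be lower, and these 3 were left out of the tests. Dio3, Thrsp, Ddit4, Glul, Per1 and Dbp, and in the other direction Sgk1 and Ppargc1a, were members picked out for mention after their values were seen. So were Fkbp5, Tsc22d3, Mt1 and Mt2, which were not called. All of these stay among those tested. Hif3a and the Y-linked genes were also chosen after their values were seen.

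Several genes known to respond to hormones were lower in PTN. Besides Hr, the thyroid hormone deiodinase gene Dio3 had 17, 17 and 11 counts in Control 1, Control 2 and Control 3 and 0 in each PTN library (edgeR adjusted p = 0.00884), and the lipogenic gene Thrsp was 2.84-fold lower, from 152 ± 21.6 to 53.7 ± 18 CPM (SD, n = 3 each, edgeR adjusted p = 0.00922). Hif3a, a hypoxia-inducible factor gene, was 5.21-fold lower, from 19.6 ± 1.32 to 3.75 ± 0.588 CPM (edgeR adjusted p = 0.00095), and the stress gene Ddit4 1.91-fold lower (edgeR adjusted p = 0.0102). The glutamine synthetase gene Glul was 2.01-fold lower, from 1283 ± 93.2 to 639 ± 167 CPM (edgeR adjusted p = 0.0229, but 0.0504 to 0.0845 without any 1 of Control 1, Control 2, Control 3 and PTN 1). In the other direction Shh was 8.25-fold, Sgk1 2.2-fold and Ppargc1a 1.61-fold higher (edgeR adjusted p = 0.00444, 0.0412 and 0.0368). Per1 and Dbp were 1.68-fold and 1.63-fold lower (edgeR adjusted p = 0.0324 and 0.0452), the counts of Dbp being in part fractional. Sgk1, Ppargc1a, Per1 and Dbp were not refitted without single libraries. Fkbp5 and Tsc22d3 were lower but not called (edgeR adjusted p = 0.272 and 0.102). Mt2 and Mt1 had positive log2 fold changes and were not called (edgeR adjusted p = 0.514 and 0.877).

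A hypothesis is that thyroid hormone or glucocorticoid signalling was lower in the PTN libraries. Of 12 tested thyroid hormone targets other than Hr, 9 had a negative log2 fold change, 3 were called lower and 2 higher, and camera put the list lower (p = 0.0287 with a preset and 0.0825 with an estimated correlation, fry p = 0.00149). Of 18 tested glucocorticoid targets other than Hif3a and Fam107a, 12 were negative, 3 were called lower and 1 higher (camera p = 0.006 with a preset and 0.109 with an estimated correlation, fry p = 0.0145). Passing with an estimated correlation as well was required only after these p-values were seen, and by the preset correlation alone both lists would have met the criterion. Neither passed the stricter one, so lower signalling stays open, and a changed share of astrocytes or an effect of PTN itself was not tested for these lists.

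Few Y-linked reads were found in PTN 3, where Ddx3y, Eif2s3y, Kdm5d and Uty together stood at 10.3% of the Control mean, against 39.3% in PTN 1, 96% in PTN 2 and 63.8% to 132% in the Control libraries. None of these genes was called between the groups (edgeR adjusted p = 0.243 to 0.423). The comparison of PTN with Control was not adjusted for this difference between libraries. A general loss of genes of that level in PTN 3 is argued against, since 1777 genes of similar mean level had a median log2 ratio to the Control mean of -0.031. Cells without a Y chromosome, such as female cells, could account for it. The X-linked genes Kdm6a, Eif2s3x, Kdm5c and Ddx3x escape inactivation. Their mean in PTN 3 lay 0.18 above the median of the other libraries on the log2 scale, but below PTN 1 and PTN 2. These levels were not corrected for the length and GC trends described below. The comparison therefore cannot decide, and female cells stay open. Loss of the Y chromosome in culture was not tested.

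Fold changes followed gene length, with Spearman's rho across genes of 0.33 with length and -0.38 with GC content, genes not being independent replicates. With GC content in the same model, the slope on log2 length of each gene's log2 CPM, taken as its deviation from the mean of the 6 libraries, was -0.12, -0.053 and -0.028 in the Control libraries and 0.069, 0.11 and 0.020 in the PTN libraries, while the slope per 10% of GC content was 0.40, -0.10 and 0.054 in Control and -0.37, -0.18 and 0.20 in PTN and did not separate the groups. Of the calls, 78.7% were kept when the length trend was removed. Its medians by eighth of length, -0.24 to 0.30, were small beside the median absolute log2 fold change of 1.13 in called genes. The removal could therefore hardly have lost most calls. By its size a smooth length trend is argued against as the whole cause of the calls. Other differences between the libraries that may go with it were not tested. The lower ribosomal protein genes, with a median length of 704 bp against 2766 bp over the tested genes, had a median log2 fold change of -0.46, and of -0.24 with length and GC trends removed, with 90.9% of members negative (camera adjusted p = 4.9e-07 with the preset correlation, though before the removal the list had 0.585 with an estimated correlation and 0.0923 by fry), so by the medians the trends may account for part of the fall but are argued against as its whole cause. The removal left the shortest eighth of the genes, with a median length of 977 bp, at a median log2 fold change of -0.057. The list was not tested with an estimated correlation or by fry after the removal. Whether the trends come from library preparation or from the cells was not tested, and an effect of PTN on ribosomal protein genes stays open.

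Other splits of the 6 libraries into 3 and 3 are 10 in number with the real one, too few for a share under 0.05. The real split gave 1052 called genes and the highest of the others 13, so that 1 of the 10 splits gave as many. At an unadjusted p under 0.05 by edgeR the real split had 3549 genes. The split that put Control 1, Control 3 and PTN 3 together had 2528 such genes, though 0 were called. The libraries therefore also differed in a way that crosses the groups, and its cause was not tested. For the fixed lists by camera the real split gave 14 and the highest other 15, so that 2 of the 10 gave as many.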
